A study of Mus musculus with 4 samples.

How the data were processed

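The samples were alkali-cleaved genomic DNA from E14tg2a mouse embryonic stem cells, per the labels. The parent line carries an auxin-inducible degron on RNaseh2a, and the derived line also carries Pole1-M630F. Each line has 2 replicates. Cells were kept for 24 h with doxycycline and auxinole and then for 12 h with doxycycline and IAA, and fragments of 300 to 2000 nt were taken from a gel, per the labels' protocols. Reads were aligned with Bowtie2 (version not given in the sources used here) to GRCm39, per the submitters' processing notes. The names of the lists carry short codes that look like settings of the zone call, but their meaning is not stated. The method of the call, what the score measures and whether parent and mutant libraries were combined are not given in the sources used here.

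Each of the 2 lists gives chromosome, first position, last position and a score, with no header. All positions are multiples of 1000, and 3451 zones of set 1 and 2694 of set 2 have the same first and last position, so the last position was read as the last 1 kb bin of the zone. The smallest step from one zone to the next was 11 kb in both sets. The score that the authors deposited is a number per zone with no stated unit. It is a whole multiple of 0.0262 in 99.98% of zones of set 1, and of 0.0219 in 100% of zones of set 2, within 0.0001. The median score was 7.23 in set 1 and 8.57 in set 2. Read counts per library were not used here, so depth is unknown and no interval for counting error could be given. Set 1 has 1 zone on Y, left out of the tests, which cover chromosomes 1 to 19 and X.

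Overlap was tested by moving all zones of set 2 on a chromosome by 1 random offset, wrapping round, while set 1 stayed in place. This keeps widths and spacing. The axis ran from the first to the last zone of either set on each chromosome, without removal of assembly gaps, since no genome of this build was used here. Overlap of at least 1 bin counted as met, and 10000 shifts were drawn for the overlap and 1000 for pair measures, regional sums and zone-free intervals. Track correlation used 200 shifts. Intervals come from a bootstrap of whole chromosomes (10000 draws). Shared and set-specific zones were compared by a two-sided sign-flip permutation test of the difference in medians over 20 chromosomes (100000 resamples), with Benjamini-Hochberg adjustment over 4 comparisons. The X chromosome was ranked among the 20 chromosomes. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

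The overlap test was tested on simulated lists with the real widths and gaps in random order. Unrelated lists kept the real numbers of zones, while planted lists lost zones that came to overlap another. Random order also removes zone-free stretches common to both sets, so false calls were not measured for lists that share them. The overlap test called 2 of 40 unrelated pairs of lists at p 0.05. It called 19 of 20 with 5% of zones planted in common and 20 of 20 with 20% planted, where the median ratio to chance was 1.07. The sign-flip test called 10 of 200 simulated comparisons without a difference and 199 of 200 with a difference of 1 SD. Those comparisons were normal values drawn around 0 or 1 SD, not zone lists. Shifted lists give differences above 0 in this comparison, so false calls of the sign-flip test for unrelated lists were not measured.

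The overlap, number, width, score agreement, shared-against-specific, per-chromosome and zone-free results, their tests and most alternatives were chosen before the data were examined. Comparisons by 10 classes of score, of the strongest zones, of score tracks, of covered bins, of regional sums and of zone flanks were added after the data were seen. The alternatives changed the overlap rule, the score minimum, the shift, the chromosomes, the correlation and the reading of the last position.

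Regions were named by a rule fixed before the data were examined: the 10 shared zones with the best mean rank and the 5 longest zone-free intervals. The extreme zones of each set and the extreme windows were named after their values were seen. The rule also called for genes, but the gene table at hand is on GRCm38.p6, so no gene position was compared with a zone and no gene is named from the data. For the same reason the planned tests of GC content, distance to transcription start sites, position relative to genes, gene orientation, gene length, zone sequence and gene lists were not run.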

Results

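Replication initiation was mapped in E14tg2a cells, a male mouse embryonic stem cell line, by polymerase-usage sequencing. The assay reads out where ribonucleotides sit in genomic DNA, since alkali breaks the strand at each of them. Pole1-M630F cells carry a mutant of DNA polymerase ε, the main leading-strand polymerase, that leaves more ribonucleotides behind. In these cells and in their parent line, RNaseh2a, a subunit of the enzyme that removes ribonucleotides from DNA, carried a degron tag that allowed its depletion. The 4 samples comprised the parent line and the Pole1-M630F line with 2 replicates each. The files analysed here were 2 lists of initiation zones, named set 1 and set 2, each with a first position, a last position and a score per zone. The libraries of replicate 1 and of replicate 2 carry the same set names, and the sources used here do not say whether the parent libraries entered the zone calls. Read depth per library is unknown from these lists. They hold no values for the parent and mutant libraries separately, so the parent line and the mutant were not compared. Nothing in the labels says that the replicates came from separate cultures, so the spread between the sets may be technical. All positions are in GRCm39 as listed, on a 1 kb grid.

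Both sets described a genome in which about 32% of the span from the first to the last zone of each chromosome lay inside initiation zones. Set 1 listed 29837 zones on chromosomes 1 to 19 and X, or 11.6 per Mb (95% interval 11.5 to 11.7, bootstrap of chromosomes). Set 2 listed 26025 zones, or 10.1 per Mb (10.02 to 10.3). The zones of set 1 had a median width of 18 kb (95% interval 18 to 19) and those of set 2 a median width of 22 kb (22 to 23). Neighbouring midpoints lay a median of 76.5 kb apart in set 1 (75 to 78) and 89.5 kb apart in set 2 (87.5 to 91). Zones covered 813 Mb, or 31.7% of the span (31.0 to 32.2), in set 1 and 838 Mb, or 32.6% (32.1 to 33.1), in set 2.

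The highest-scoring zone of each set lay on a different chromosome, while the widest zone of each lay on chromosome 10. The highest score of set 1 belonged to chromosome 6, 28389000 to 28520000, at 216.9, and that of set 2 to chromosome 7, 62050000 to 62230000, at 270.2. The widest zones were those at 85698000 to 85940000 in set 1 (243 kb) and at 56191000 to 56413000 in set 2 (223 kb). Scores are the authors' own and their scale is not given in the sources used here, so score values, differences and sums have no known unit and levels are not compared between the sets. Wide zones had high scores, with a rank correlation across zones of 0.943 in set 1 and 0.950 in set 2. Set 1 held 2320 more zones of up to 10 kb than set 2 and 2279 more of over 10 to 40 kb. The difference for zones wider than 40 kb was -787, that is, fewer in set 1. As each set is a single list, no test between them was made.

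The next comparison asked whether both sets place initiation zones at the same positions. By any overlap of at least 1 bin, nearly all of the strongest zones met the other set and most weak zones did not. Of the 10% of zones with the highest scores, 98.6% in set 1 and 99.4% in set 2 met a zone of the other set, against 82.9% and 88.3% after one list was moved along the chromosomes. Of the 10% with the lowest scores, 26.9% of the set 1 zones met set 2, below the 33.4% of shifted lists, and 25.1% of the set 2 zones met set 1, below 32.6%. Both differences among the strongest zones reached one-sided circular-shift permutation p = 0.0001 for more overlap, the smallest that 10000 shifts can give. Both among the weakest reached one-sided circular-shift permutation p = 0.0001 for less overlap, a direction that was not planned. Median width was 76 kb in set 1 and 86 kb in set 2 for the highest 10%, against 1 kb for the lowest. By midpoints within 10 kb, fewer of the highest 10% were met, 39.4% in set 1 and 40.2% in set 2. Shifted lists gave 20.6% and 23.6% under that rule. The deficit of the weakest zones also depended on the rule. By midpoints within 10 kb, the lowest 10% of set 1 lay within the range of shifted lists (20.33% against 20.62%). The lowest 10% of set 2 still lay below that range (21.37% against 23.67%, one-sided circular-shift permutation p = 0.0031 for fewer zones met). The 20% of zones with the lowest scores lay within the range of shifted lists by midpoints in both sets (20.6% against 20.6%, and 22.97% against 23.65%). By any overlap, the lowest 20% lay 6.20 and 5.69 points above random placement in the space that the other zones of their own set leave free. By midpoints this excess was 3.44 and 2.77 points. With placement also kept within 500 kb, it was 2.52 in set 1 and 1.49 in set 2, where shifted lists reached up to 1.95. Across all zones, 56.2% of set 1 (16756 of 29837) met set 2, against 52.8% by chance (95% range 52.4 to 53.3), a ratio of 1.06. For set 2 the share was 59.9% (15592 of 26025) against 56.8% (56.3 to 57.3), a ratio of 1.05. Each had a one-sided circular-shift permutation p = 0.0001, the smallest possible.

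**Figure D1:**
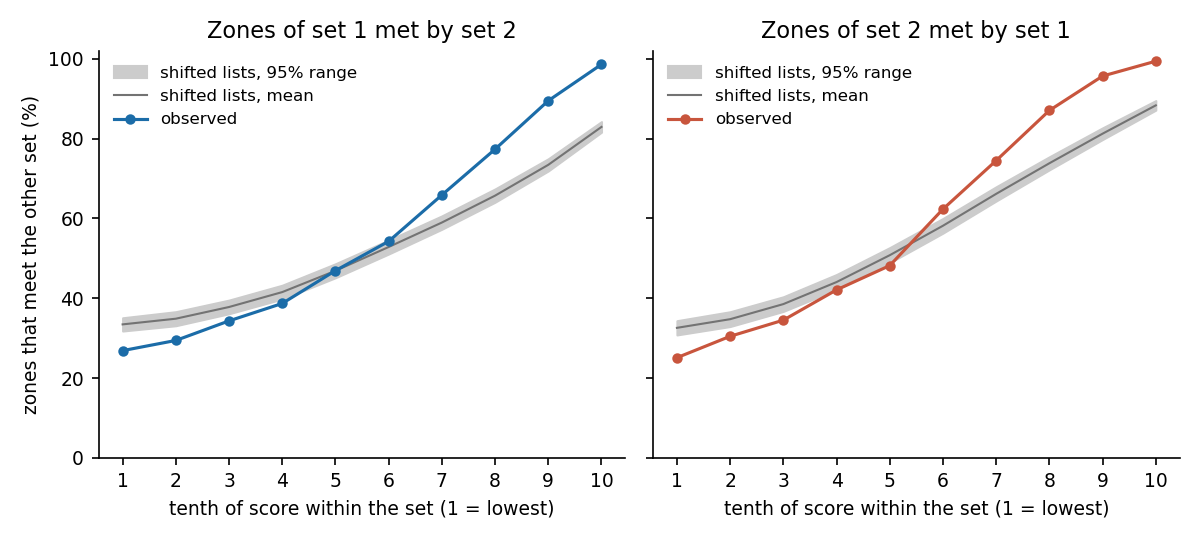
Percentage of zones that meet a zone of the other set (vertical axis) in each of 10 classes of score within the set (horizontal axis), for set 1 on the left and set 2 on the right; points are observed shares, and the grey line and band are the mean and 95% range of lists shifted along the chromosomes. The observed share rises from 26.9% to 98.6% in set 1 and from 25.1% to 99.4% in set 2, crossing the shifted lists near the middle of the scores.

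Stricter rules gave larger ratios to chance. A reciprocal overlap of 50% or more was met by 5311 zones of set 1, 17.8% against 8.49% by chance, a ratio of 2.10. When only the 10% of zones with the highest scores of each set were kept, 1573 of 2985 zones of set 1 met set 2, 52.7% against 17.6%, a ratio of 3.002. Each of these had a one-sided circular-shift permutation p = 0.0001. Bins covered by both sets added up to 413 Mb against 266 Mb by chance (95% range 263 to 269), a ratio of 1.55, with a two-sided circular-shift permutation p = 0.002, the smallest that 1000 shifts can give.

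Chromosome 2 held the shared zone with the best mean rank. In the authors' deposited table of set 1 this zone spanned 63684000 to 63848000 with a score of 204.1, and in the authors' deposited table of set 2 it spanned 63716000 to 63823000 with a score of 235. Chromosome 19 held the next, at 31006000 to 31143000 in set 1 and 31022000 to 31190000 in set 2, with scores of 187 and 229 in the authors' deposited table of each set. The X chromosome held the next 3, which began at 19157000, 166886000 and 14459000 in set 1 in the authors' deposited table. The others among the 10 best-ranked began at 7735000 on chromosome 5, 110672000 on chromosome 1, 48643000 on chromosome 11, 23637000 on chromosome 10 and 62318000 on chromosome 17, as set 1 of the authors' deposited table lists them. Genes at these zones were not analysed here, because the gene table at hand is on another genome build.

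**Figure D2:**
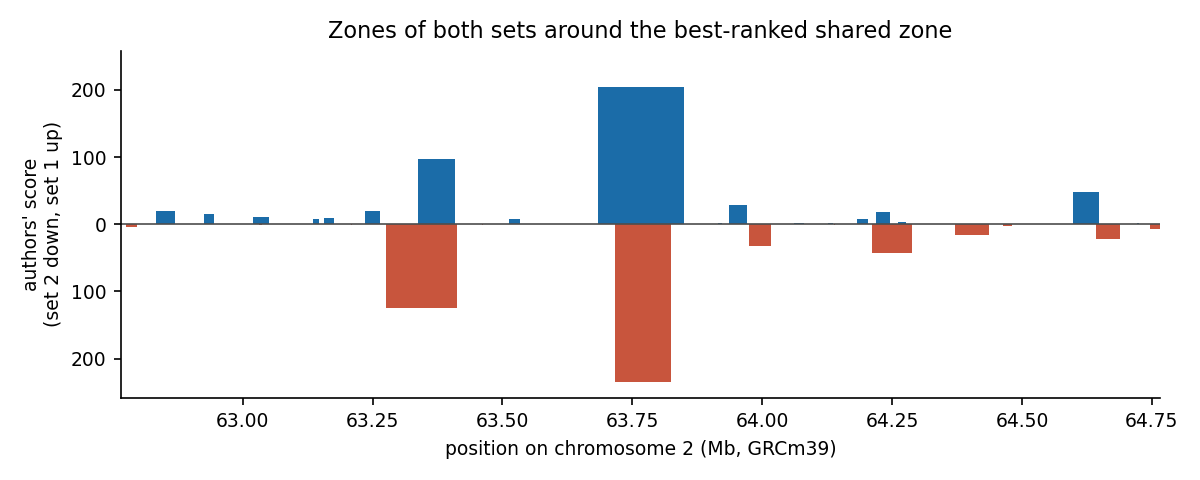
Zones of set 1 (blue, upward) and set 2 (red, downward) in a window of 2 Mb on chromosome 2 (horizontal axis, Mb, GRCm39), with the width of a bar giving the zone's extent and its height the authors' score (vertical axis, no unit given). The zone from 63684000 to 63848000 in set 1 faces one of 108 kb in set 2, and the window holds 27 zones of set 1 and 16 of set 2.

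Zones strong in both sets formed a sparse map across all 20 chromosomes. Pairs of overlapping zones that were both among the highest 10% of scores numbered 1578, against 525 with shifted lists (95% range 488 to 568). Their midpoints differed by a median of 14 kb, against 43.1 kb in shifted lists, each with a two-sided circular-shift permutation p = 0.002, the smallest possible. The shared intervals lay a median of 1085 kb apart (interquartile range 580 to 2014 kb). Their density ran from 0.481 per Mb on chromosome 8 to 0.782 per Mb on chromosome 13, with 0.662 per Mb on X.

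Signal tracks built from the zone scores also coincided along the chromosomes. The correlation across 1 kb bins was 0.481 (95% interval 0.464 to 0.496, bootstrap of chromosomes), against at most 0.0157 in 200 shifts, with a one-sided circular-shift permutation p = 0.005, the smallest possible. It was highest on chromosome 13 (0.541) and lowest on X (0.407), with chromosome 8 lowest among the autosomes (0.435). All 246 windows of 10 Mb exceeded 0.123, the 95th percentile of shifted lists. Chromosome 13 from 103107000 to 113106000 had the highest value (0.726), and chromosome 7 from 13095000 to 23094000 the lowest (0.224). These bins and windows are not independent replicates.

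**Figure D3:**
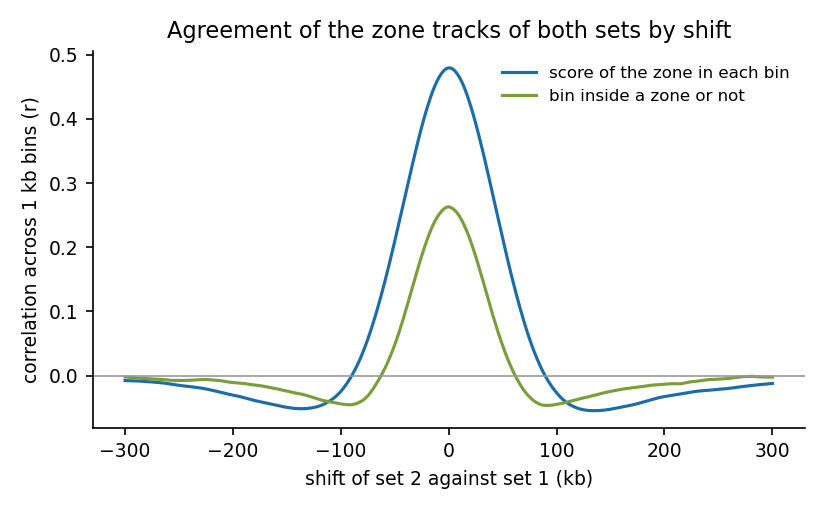
Correlation between both sets across 1 kb bins (vertical axis, r) as set 2 is moved against set 1 (horizontal axis, kb), for tracks that hold the score of the zone in each bin (blue) and for tracks that record only whether a bin lies inside a zone (green). Both curves peak at 0 kb, and the score curve has a full width of 91 kb at the middle of its height and its lowest value, -0.0546, at 135 kb.

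Whether a zone with a high score in one set also had a high score in the other was asked across the 18712 intervals where zones of both sets overlap. The rank correlation was 0.201 (95% interval 0.185 to 0.215, bootstrap of chromosomes), while shifted lists gave -0.189. Among the 5311 pairs with a reciprocal overlap of 50% or more it was 0.735 (0.722 to 0.749). This rule pairs zones of similar width, and shifted lists alone gave 0.575 (95% range 0.546 to 0.6002) under it. The Pearson correlation of log scores over all pairs was 0.0745, against -0.199 in shifted lists. Zones are not independent replicates, so no p-value accompanies these correlations.

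Zones found in both sets were wider and stronger than zones found in 1 set only, on 20 of 20 chromosomes. Shared zones of set 1 had a median score of 19.4 and a median width of 33 kb, against 2.10 and 7 kb for those only in set 1. In set 2 the values were 24.0 and 41 kb against 1.75 and 8 kb. The mean difference over chromosomes was 26.3 kb ± 2.54 (SD) in width for set 1 and 34.1 kb ± 2.54 for set 2. All 4 comparisons of width and score had a Benjamini-Hochberg adjusted p = 1e-05 in a two-sided sign-flip permutation test over 20 chromosomes, the smallest that its resamples can give. A wide zone meets another list more easily by chance, and shifted lists alone gave width differences of 19.4 kb in set 1 and 27.0 kb in set 2. They also gave most of the difference in score, 12.0 of an observed 17.2 in set 1 and 16.7 of 22.4 in set 2, so the sign-flip test against 0 does not separate the pattern from chance overlap. The observed differences in width and in score exceeded those of all shifts, with a two-sided circular-shift permutation p = 0.002 in both sets.

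The X chromosome, present in 1 copy in this male line, was compared with the 19 autosomes. X had more zones per Mb than the autosome mean in both sets, with a lower median width and a higher median score. Set 1 listed 11.8 zones per Mb on X against 11.6 ± 0.299 (SD over 19 autosomes), and set 2 listed 10.7 against 10.1 ± 0.206. Zones covered 27.7% of X in set 1 against 32.0% ± 0.899, and 30.0% in set 2 against 32.9% ± 0.794. X had the lowest share of the 20 chromosomes in both sets, and chromosome 14 the lowest among autosomes, at 29.8% and 30.9%. Without zone-free intervals of 500 kb or more, X was still lowest in set 1 (29.5%) but not in set 2, where it had 31.9% against 31.4% for chromosome 14. The median width on X was 16 kb in set 1 and 18 kb in set 2, against autosome means of 18.8 kb and 22.8 kb. Chromosome 14 had the lowest median width among autosomes, at 16 kb and 19 kb, so narrow zones were not particular to X. The median score on X was 8.001 in set 1 against an autosome mean of 7.25 ± 0.610, and 9.76 in set 2 against 8.60 ± 0.812, with a two-sided rank permutation p = 0.2 in each set. For covered length, the two-sided rank permutation p was 0.1 in each set, which is the smallest that 20 chromosomes allow, so this design cannot pass 0.05. For zones per Mb, the rank permutation p was 0.6 in set 1 and 0.1 in set 2. The span used for zones per Mb kept the long zone-free intervals, 9.995 Mb of them on X. Ranks of zones per Mb without them were not computed.

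**Figure D4:**
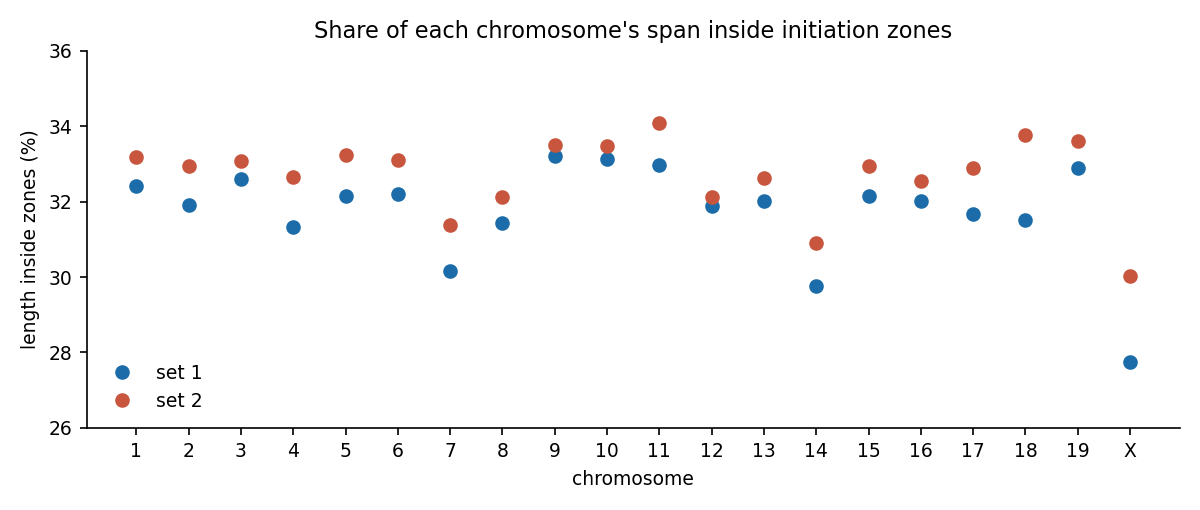
Share of the span between the first and last zone that lies inside zones (vertical axis, %, starting at 26) for each chromosome (horizontal axis), with 1 point per set. X lies lowest in both sets, at 27.7% and 30.0%, and chromosome 14 is next, at 29.8% and 30.9%.

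Long stretches without a zone of either set lay on a few chromosomes. There were 23 zone-free intervals of 500 kb or more, 21.4 Mb in all. Shifted lists gave 1.02 (95% range 0 to 4), with a one-sided circular-shift permutation p = 0.001, the smallest possible. Set 1 alone had 28 such intervals and set 2 alone had 27. The test against shifts thus measures whether these stretches coincide between the sets. Whether they gather by chromosome was not tested. Of the 23 intervals free of zones in both sets, X held 10, chromosome 4 held 4, chromosomes 7 and 14 held 3 each, chromosome 5 held 2 and chromosome 2 held 1. The longest lay on X from 26869000 to 29340000 (2472 kb), followed by chromosome 5 from 93881000 to 95975000 (2095 kb) and X from 123158000 to 124914000 (1757 kb). Chromosome 7 from 20846000 to 22482000 (1637 kb) and chromosome 2 from 175022000 to 176392000 (1371 kb) came next. Assembly gaps and unmappable sequence were not analysed here, so these intervals can include either. With intervals lacking a shared zone in place of those lacking any zone, the count was 153 and the longest lay on chromosome 7 (3339 kb). With the zones of set 2 alone, the longest zone-free interval also lay on chromosome 7 (3227 kb).

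Regional strength also recurred between the sets. Across 2556 windows of 1 Mb, the rank correlation of the summed scores was 0.570, against 0.0186 with shifted lists (95% range -0.0207 to 0.0637; one-sided circular-shift permutation p = 0.001, the smallest possible). The number of zones per window correlated less, at 0.222. Assembly gaps and unmappable sequence were left in and could lower the sums of both sets alike. How much they add to this agreement, or to that of the overlaps and tracks, was not tested. The strongest windows were chromosome 14 from 45060000 to 46059000, at 2.03 times the mean summed score, and chromosome 1 from 66075000 to 67074000, also at 2.03 times. Most windows were far less extreme, with a median of 0.995 and an interquartile range of 0.815 to 1.18 times the mean.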

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

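The tests of the highest 10% of scores, plain interval ends, set 2 zones met by set 1, covered bins, tracks, regional sums, X without long zone-free intervals, chance values of the score correlations and of shared against set-specific zones under other rules, and zone number, width and spacing with either set left out were chosen after the results were seen; the others were planned. The overlap of the sets stayed above chance under all 10 alternatives run, with ratios from 1.05 to 3.002, and shared zones exceeded all 1000 shifted lists in width and score under reciprocal overlap, midpoint distance and means per chromosome. By midpoints, the width difference was 9.55 kb in set 1 and 10.9 kb in set 2, where shifted lists gave 0.0918 and -0.00977. Merging zones closer than 10 kb joined none, so that alternative tested nothing. With scores at or above the median of their own set, the mean number of zones per set was 13970, the median width 47 kb and the median spacing 158 kb, by construction of a shorter list. Spacing between zone edges was 52 kb. Read as plain interval ends, which drops zones of 1 bin, width was 24 kb and spacing 94.3 kb. The score correlation across shared zones moved to 0.735 with reciprocal overlap, where shifted lists gave 0.575 because the rule matches widths. It was 0.396 with midpoints within 10 kb and 0.0745 with Pearson's r of log scores, against -0.139 and -0.199 in shifted lists, and the cause of these moves was not tested. The track correlation was 0.503 in 10 kb bins and 0.264 for covered bins without scores, and the regional correlation 0.636 in 5 Mb and 0.668 in 10 Mb windows. The ratio of X to the autosome mean, 1.04 by zone count, reversed to 0.891 by covered length, because zones on X were narrower, and to 0.944 without long zone-free intervals; it ran from 1.02 to 1.06 with either set left out. Intervals without a shared zone numbered 153, the longest 3339 kb, by construction; with either set left out the longest was 2535 to 3227 kb, on chromosome 7 in place of X without set 1.

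No paired analysis was possible because the lists hold zones per set and no values for the parent and mutant libraries separately. Whole chromosome length as the denominator was not run, nor were the alternatives of the planned gene, GC and sequence results. Depth is unknown and limits what weak zones can show.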

Other observations

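The tests of coordinate offset, of low-scoring zones against shifted lists, of X track agreement, of split zones, of score steps, of zone flanks, of evenness and of neighbouring scores were chosen after the results they bear on had been seen; the tests of midpoint distance, long zone-free intervals and exclusion by strong zones had their bounds set before their values were seen. The use of free space as a test of weak zones at chance positions, with its midpoint and local versions, was decided only after the first of these values was known. The bound for that explanation was reworded after the values were seen, since its earlier wording also accepted any deficit.

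Strong zones stood in wider empty surroundings than weak ones. The mean gap to both neighbours had a median of 69.5 kb among the highest 10% of scores of set 1 and 44.5 kb among the lowest 10%, and of 83 kb and 51 kb in set 2. The rank correlation of score and gap across zones was 0.237 in set 1 and 0.271 in set 2, each with a two-sided permutation p = 0.001, the smallest that 1000 shuffles within chromosomes can give. Zones among the highest 25% of scores were spread more evenly over 1 Mb windows than in random order, with a variance over mean of 0.512 against 0.661 (95% range 0.628 to 0.694) in set 1 and 0.562 against 0.654 (0.621 to 0.687) in set 2. All zones together were spread less evenly than in random order, at 0.598 against 0.477 and 0.617 against 0.454. Each of these 4 had a two-sided permutation p = 0.002, the smallest possible. Scores of direct neighbours were nearly unrelated, at -0.00769 in set 1 (permutation p = 0.2, adjusted p = 0.3) and 0.0248 in set 2 (permutation p = 0.001, adjusted p = 0.006).

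Of the 16 windows of 10 Mb on X, 11 were among the 61 with the lowest track correlation of all 246 windows. Of the windows of 1 Mb, 5 held no zone in either set: chromosome 2 from 175071000, chromosome 5 from 94112000, chromosome 7 from 21095000, and X from 27072000 and from 28072000. The Y chromosome had 1 zone, in set 1 only, from 90729000 to 90757000 with a score of 25.1.

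Both sets overlapped by only 1.06 times chance when every zone counted, and a coordinate offset is argued against, since the score tracks correlated best at a shift of 0 kb. Weak zones at chance positions stay open in both sets. The lowest 20% of scores were placed at random in the space that the other zones of their own set leave free. They met the other set 6.20 and 5.69 points more often than under such placement. This excess was beyond 40 shifted lists per set (at most 1.48 and 2.39). The same held for midpoints (3.44 and 2.77, at most 1.04 and 1.40) and for placement within 500 kb (5.12 and 4.26, at most 1.80 and 1.59). With both together set 1 exceeded the shifted lists (2.52, at most 0.758) and set 2 did not (1.49, at most 1.95). Random placement can also fill stretches that are empty in both sets, such as the long zone-free intervals. Shifted lists do not keep these stretches in common, so how much of the excess comes from them is unknown. Against whole shifted lists the same zones met the other set less often by any overlap (28.1% against 34.1%, 27.7% against 33.6%) and about as often by midpoints (20.6% against 20.6%, 22.97% against 23.65%). The lowest 10% of scores of set 2 lay below shifted lists by midpoints as well (21.37% against 23.67%), while those of set 1 did not leave their range (20.33% against 20.62%). Free-space placement itself gave 21.9% in set 1, so exclusion by strong zones of the same set may account for the deficit against shifted lists, although the observed share lay above the range that this explanation had been given (20.9 to 22.9%). Wide zones that meet by chance may also hold the ratio down. In shifted lists the share of set 1 zones met was 33.4% in the lowest 10% of scores (median width 1 kb). It was 82.9% in the highest 10% (76 kb), which left strong zones little room above chance. With midpoints within 10 kb the ratio was 1.22, between the bounds set beforehand, so how far width explains it stays open. No biological explanation was tested.

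The X chromosome had the lowest share of its length inside zones in both sets. Without its zone-free intervals of 500 kb or more the share was 29.5% in set 1, still below the 30.3% of chromosome 14, and 31.9% in set 2, inside the autosome range that starts at 31.4%. Long zone-free intervals may thus account for part of the low share. They do not account for all of it in set 1, and in set 2 X still ranked 2 from the lowest, below the autosome mean of 33.0% ± 0.697 (SD). Lower depth from the single copy of X in this male line cannot be told apart from a property of X, since depth per chromosome was not used here: the track correlation on X (0.407) was the lowest of the 20 chromosomes, but the median score on X lay above the autosome mean in both sets (8.001 against 7.25, 9.76 against 8.60). The biology of a single X was not tested.

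Set 1 listed 3812 more zones than set 2, 14.6% more, and narrower ones. Splitting of wide zones of set 2 stays open, since the counts below cannot exclude it. Zones of set 2 that met 2 or more zones of set 1 numbered 2673, which was 238 more than in shifted lists. Shifting does not keep the wide empty surroundings of strong zones aligned between the sets, so this chance level may be too high. Joining zones that meet the same zone of the other set, done in both sets, lowered the surplus by a net 1164, 195 more than in shifted lists. This net value always equals the difference between the sets in zones met, so it does not measure splitting. A lower depth of set 1 stays open: 1 score step was 1.20 times larger in set 1, but library totals were not used here and what a step stands for is unknown. No biological explanation was tested, and which libraries entered each call is not given in the sources used here.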
